A study of Homo sapiens with 3 samples.

How the data were processed

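RNA from HK-2 cells was measured on Affymetrix arrays of 7129 probe sets, with 1 array for control cells, 1 for cells at 12 h of cyclosporine A and 1 for cells at 48 h. The groups and the 12 h and 48 h times come from the labels; the control's label gives no time, and 0 h was assumed for it from the series title. The table deposited by the authors gives 1 linear intensity per probe set and array. The software and settings behind these intensities are not given in the sources used here. Probe-level values and detection calls were not used here. The deposited intensities had not been brought to one scale, since their 2% trimmed means were 57.9 on the control array, 73.6 on the 12 h array and 80.6 on the 48 h array, which is more than the 5% apart allowed by the rule set beforehand. All 3 value columns were mapped to a sample, and 0 columns were left unmapped.

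Each array was multiplied by a factor (1.21, 0.952 and 0.869 for control, 12 h and 48 h) to a common 2% trimmed mean of 70.1, leaving out 58 control probe sets. Values were then floored at the 40th percentile of the pooled scaled values, 11.4 units, and turned into log2 values. Probe sets were named through the platform annotation given with the data: 5709 probe sets had 1 gene symbol, 321 had several and 1099 were not listed. Entrez identifiers of 5704 of the 5709 matched the RefSeq gene table used, 5 did not, and 0 symbols needed an update. Probe sets with several symbols or none were not named. For each of 4993 genes the probe set with the highest mean over the 3 arrays was used, and a gene counted as measured in a comparison when at least 1 of its 2 arrays lay above the floor. No coordinates are given, because the build of that gene table was not matched to any build in the files.

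With 1 array per group there was no test. A gene was counted by size, at a ratio of at least 2-fold, in 3 comparisons: 12 h over control, 48 h over control and 48 h over 12 h. A gene at the floor on 1 array has only a bound, computed from the floor. A set of 28 gene lists was fixed for kidney cells and this compound, and each list with at least 5 measured members was described by its median log2 ratio and by the percentile of that median among 10000 random lists of the same size, drawn within 20 bins of mean signal. A list was said to stand apart below percentile 1 or above percentile 99. Of 26 lists tested per comparison 0.52 would pass these limits by chance if the genes of a list varied independently. At 12 h 5 passed, at 48 h 6 and between 12 h and 48 h 7. The 0.52 does not cover lists of genes that vary together. The percentile describes these arrays and carries no inference about other cultures.

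Named genes followed a rule. For each exposure time over control they were the 10 largest differences upward and the 10 downward among genes at least 2-fold different and above the floor on both arrays, and up to 5 bounds per direction. Added to these were up to 4 members of each list that stood apart or held at least 3 members 2-fold different. For 48 h over 12 h they were the 5 largest in each direction. PPP3CA, PPP3CB, PPIA, RCAN1, TGFB1, CDH1, VIM, FN1, ACTA2, HSPA5, DDIT3, HMOX1 and CDKN1A were always included where measured; PPIA and DDIT3 had no probe set with a symbol of their own here. Members of lists with too few measured genes were given as values. The groups, lists, size rule, rule for named genes and other settings to be tried were fixed before the data were examined.

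The 7 other settings fixed in this way were scaling to a common median, quantile normalization, cyclic loess (limma 3.58.1 in R 4.3.3, after adding 1), a floor at the 25th or the 60th percentile, a pseudocount of 1.62 (the pooled 10th percentile) with no floor, and the mean of all probe sets of a gene. Random lists under these settings numbered 2000. Scaling on the hybridisation controls was added after the data were seen. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

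The steps were tested on simulated data for 48 h over control with 3543 genes. The 2-fold rule found 100 of 100 genes simulated as 4-fold higher, 46 of 50 simulated as 4-fold lower and 6 of 50 simulated as 1.5-fold higher, and it called 88 of 3343 unchanged genes. Among 200 simulated lists of 20 genes, 99.0% of those raised by 0.5 on the log2 scale and 1.0% of unchanged ones stood apart. The simulated changes of single genes were placed only where mean signal exceeded 2 times the floor, so dimmer genes are not covered. Unchanged lists were random genes with independent scatter, so their rate does not cover lists of genes that vary together.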

Results

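HK-2 cells, an established line of human kidney proximal tubule epithelium, were profiled on 3 Affymetrix arrays during exposure to cyclosporine A. Cyclosporine A is an immunosuppressant that binds cyclophilins and inhibits the phosphatase calcineurin, and kidney toxicity limits its use. The arrays held control cells, cells at 12 h of exposure and cells at 48 h of exposure, with 1 array each. The labels used here do not give the dose. The control's own label gives no time, and it was taken as the 0 h point that the series title lists. There were no replicates, so no error, test or replicate check can be given, and every difference is one between individual arrays whose number limits the precision. Whether the control cells were harvested at the start or kept in culture longer is not stated, so a ratio over control can hold hours in culture as well as exposure.

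The median deposited signal was 16 on the control array, 19.4 on the 12 h array and 22.1 on the 48 h array, and the arrays were therefore brought to a common trimmed mean. After scaling, 3303, 3268 and 3272 of 4993 named genes lay above the floor of 11.4 scaled units on the control, 12 h and 48 h arrays. Log2 signals correlated across genes with r = 0.974 between control and 12 h, 0.949 between control and 48 h, and 0.952 between 12 h and 48 h; genes are not independent replicates. Some signs of RNA quality moved with exposure. The 18S ribosomal RNA control probe set read 792 scaled units in the control, 3754 at 12 h and 2252 at 48 h. The 3' over 5' ratio of the actin control was 2.76, 1.90 and 1.94 on the same arrays, while that of GAPDH was 1.16, 1.14 and 1.09. Scaling on 9 probe sets of the bacterial hybridisation controls, an alternative chosen after the data were seen, moved the median log2 ratio of all genes from -0.03 to 0.51 at 12 h over control, from 0.01 to -0.23 at 48 h over control and from 0.04 to -0.75 at 48 h over 12 h. All directions given here are therefore relative to the bulk of genes on each pair of arrays and not to RNA per cell.

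At 12 h, genes of protein folding in the endoplasmic reticulum and of amino acid supply were higher than in the control. Genes of mitosis and of a mainly cytosolic heat shock list were lower. HSPA5, the main chaperone of the endoplasmic reticulum, read 308 scaled units in the control and 614 at 12 h, and ASNS, which makes asparagine, read 102 and 284. CDK1, the kinase that drives entry into mitosis, read 65.1 in the control and 28.4 at 12 h. TGFB1, a cytokine central to kidney fibrosis, was 2.41-fold higher, at 34.2 and 82.5 scaled units.

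All 16 measured members of the endoplasmic reticulum chaperone and unfolded protein response list were higher at 12 h, with a median log2 ratio of 0.43 that lay at percentile 99.99 of 10000 random lists matched on signal. MANF, a secreted stress protein, was 2.02-fold higher and was the 1 member past the 2-fold rule; HSPA5 fell just short of it with a log2 ratio of 0.997, HYOU1 was 1.90-fold higher and HERPUD1 1.80-fold higher. Among 22 measured ATF4 and amino acid response genes 17 were higher, with a median of 0.58 at percentile 100. ASNS was 2.77-fold higher, the cysteinyl-tRNA synthetase CARS1 1.98-fold, the serine synthesis enzyme PSPH 1.95-fold and the mitochondrial carboxykinase PCK2 1.95-fold. Of 29 measured G2/M and mitosis genes 26 were lower and 5 of them at least 2-fold, with a median of -0.63 at percentile 0.0. The spindle protein DLGAP5 was 2.76-fold lower, the survivin gene BIRC5 2.43-fold, the hyaluronan receptor HMMR 2.31-fold and CDK1 2.29-fold. Of 16 measured cytosolic heat shock genes 13 were lower, with a median of -0.37 at percentile 0.01; BAG1 was 1.84-fold lower, DNAJA1 1.56-fold and HSPH1 1.47-fold, and HSPE1 had a log2 ratio of -0.57. The 18S probe set was 4.74-fold higher on the same 12 h array than on the control array. These 4 lists kept their direction and stayed beyond the 1st or 99th percentile under all 7 other settings fixed beforehand.

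Epithelial junction and keratin genes had a median of 0.22 at 12 h, at percentile 99.24, with 9 of 16 members higher and 7 lower. The call held in 2 of these 7 settings, and the percentile was 78.25 with the higher floor. KRT7 was 1.84-fold higher, the E-cadherin gene CDH1 1.55-fold higher from 11.9 scaled units, close to the floor, and the desmosomal cadherin DSG2 1.44-fold higher, while CTNNB1, which encodes beta-catenin, was 1.68-fold lower. The list of TGF-beta ligand, receptor and response genes did not stand apart, with a median of -0.18 at percentile 6.76. Within it SMAD2, a signal transducer of the pathway, was 2.40-fold lower at 12 h, while GDF15 was 1.72-fold and INHBA 1.68-fold higher. SMAD2 and INHBA read 83.67 and 19.64 at 48 h, near their control values of 78.85 and 20.92. Their differences therefore rest on the 12 h array alone.

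In all, 35 genes were at least 2-fold higher and 48 at least 2-fold lower at 12 h among 3473 measured genes. With both arrays above the floor the largest differences upward were those of TNNI1, a muscle troponin, at 5.70-fold, the peroxisomal thiolase ACAA1 at 3.51-fold and EPAS1, the hypoxia-inducible factor HIF-2 alpha, at 3.48-fold. They were followed by ASNS, the cargo lectin LMAN2 at 2.49-fold, the lysosomal mannosidase MAN2B1 at 2.45-fold, TGFB1, GET3 at 2.41-fold, SUPT6H at 2.27-fold and the mitochondrial carrier SLC25A11 at 2.26-fold. TNNI1 read 13.2 in the control and 9.56 at 48 h, so its 75.2 at 12 h rests on that array alone. EPAS1 read 11.5 in the control, close to the floor. The largest differences downward were those of the deubiquitinase USP4 at 4.09-fold and HLA-DQB2 at 4.07-fold, whose probe set name marks relaxed design rules, then APLP1 at 3.46-fold, ADRA2B at 3.29-fold, the clock-regulated factor DBP at 3.18-fold and the autophagy receptor CALCOCO2 at 3.03-fold. SOX3 was 2.83-fold lower, DLGAP5 2.76-fold, CNTN2 2.75-fold and SRRD 2.60-fold. SOX3 read 11.6 at 12 h, close to the floor. At 48 h APLP1, ADRA2B, DBP and CALCOCO2 read 63.7, 42.2, 67.6 and 80.9, against 61.6, 42.6, 39.3 and 72.3 in the control. Their falls therefore also rest on the 12 h array alone. USP4 and HLA-DQB2 stayed low at 48 h, at 29.1 and 35.1, so their falls at both times rest on the single control array. Among genes at the floor on 1 array, EVX1 was at least 3.91-fold higher at 12 h, KCNMB1 at least 3.33-fold, TBL3 at least 2.97-fold, SLC6A3 at least 2.77-fold and MUTYH at least 2.43-fold. POU2F2 was at least 3.28-fold lower, ID1 at least 2.79-fold, TMEM106A at least 2.57-fold, FZD5 at least 2.42-fold and PKLR at least 2.39-fold. SLC6A3 and MUTYH were at the floor again at 48 h. ID1 and FZD5 read 35.7 and 32.3 at 48 h, above their control values of 31.8 and 27.6. The bounds of these genes rest on the 12 h array alone.

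The 2-fold genes at 12 h were dim, with a median mean signal of 25.9 against 50.2 for all measured genes, and raising the floor to the 60th percentile left 11 higher and 10 lower; median scaling gave 50 higher and 43 lower, and the hybridisation controls 337 and 16. Second probe sets of the same genes followed the first poorly at 12 h, with r = 0.147 across 184 genes, and 1 of 4 such 2-fold genes had its other probe set on the same side by at least 0.32 on the log2 scale.

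At 48 h, genes of mitosis, DNA replication, the proteasome and cholesterol and fatty acid synthesis were lower than in the control, and proximal tubule genes and amino acid response genes were higher. DPP4, a peptidase of the tubule brush border, read 43.4 scaled units in the control and 190.2 at 48 h. CCNB1, the mitotic cyclin, read 312 in the control and 108 at 48 h, and SQLE, an oxygenase of cholesterol synthesis, read 581 and 240.0. The calcium-binding protein gene S100A2 read 894 and 209.6. TGFB1 was 2.80-fold higher than in the control, at 95.7 scaled units. Its rises at both times rest on the single control array.

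Of the 29 measured G2/M and mitosis genes 28 were lower at 48 h and 11 of them at least 2-fold, with a median log2 ratio of -0.90 at percentile 0.0. CDK1 was 3.30-fold lower, CCNB1 2.88-fold, the anaphase activator CDC20 2.86-fold and HMMR 2.67-fold. Of 31 measured DNA replication and G1/S genes 24 were lower and 3 at least 2-fold, with a median of -0.48 at percentile 0.0; the ribonucleotide reductase subunit RRM2 was 2.86-fold lower, the origin licensing factor CDC6 2.74-fold, the polymerase subunit POLA1 2.26-fold and the helicase subunit MCM4 1.84-fold. Of 27 measured proteasome genes 26 were lower, none of them 2-fold, with a median of -0.42 at percentile 0.02. PSMD14 was 1.97-fold lower, PSMD1 1.93-fold, PSMC1 1.77-fold and PSMC3 1.76-fold. Of 17 measured cholesterol and fatty acid synthesis genes 14 were lower and 3 at least 2-fold, with a median of -0.41 at percentile 0.48. NSDHL was 2.84-fold lower, SQLE 2.42-fold, EBP 2.04-fold and MSMO1 1.88-fold, all enzymes of the later steps of sterol synthesis.

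Of 21 measured ATF4 and amino acid response genes 17 were higher at 48 h, with a median of 0.43 at percentile 99.92. CARS1 was 2.65-fold higher, the amino acid transporter subunit SLC3A2 1.96-fold, the alanyl-tRNA synthetase AARS1 1.91-fold and ASNS 1.72-fold. Of 12 measured proximal tubule genes 9 were higher and 3 at least 2-fold, with a median of 0.55 at percentile 99.9. DPP4 was 4.38-fold higher, the arginine synthesis enzyme ASS1 2.17-fold, the renal lineage factor PAX8 2.03-fold and VCAM1 1.55-fold. The 18S probe set was 2.84-fold higher on this array than on the control array, and the actin 3' over 5' ratio was 1.94 against 2.76. The proximal tubule list lay inside the random range with the floor at the 25th percentile, at percentile 98.08, and with a pseudocount and no floor, at 86.65, and the cholesterol and fatty acid synthesis list with the floor at the 60th percentile, at 1.80.

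Endoplasmic reticulum chaperone genes had a median of 0.01 at 48 h (below 0 with the floor at the 60th percentile), at percentile 56.42, with 8 of 16 members higher and 8 lower. HSPA5 read 273.5 scaled units at 48 h and MANF 161, below their control levels of 308 and 199.9. Their rises at 12 h therefore rest on the 12 h array alone.

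**Figure D1:**
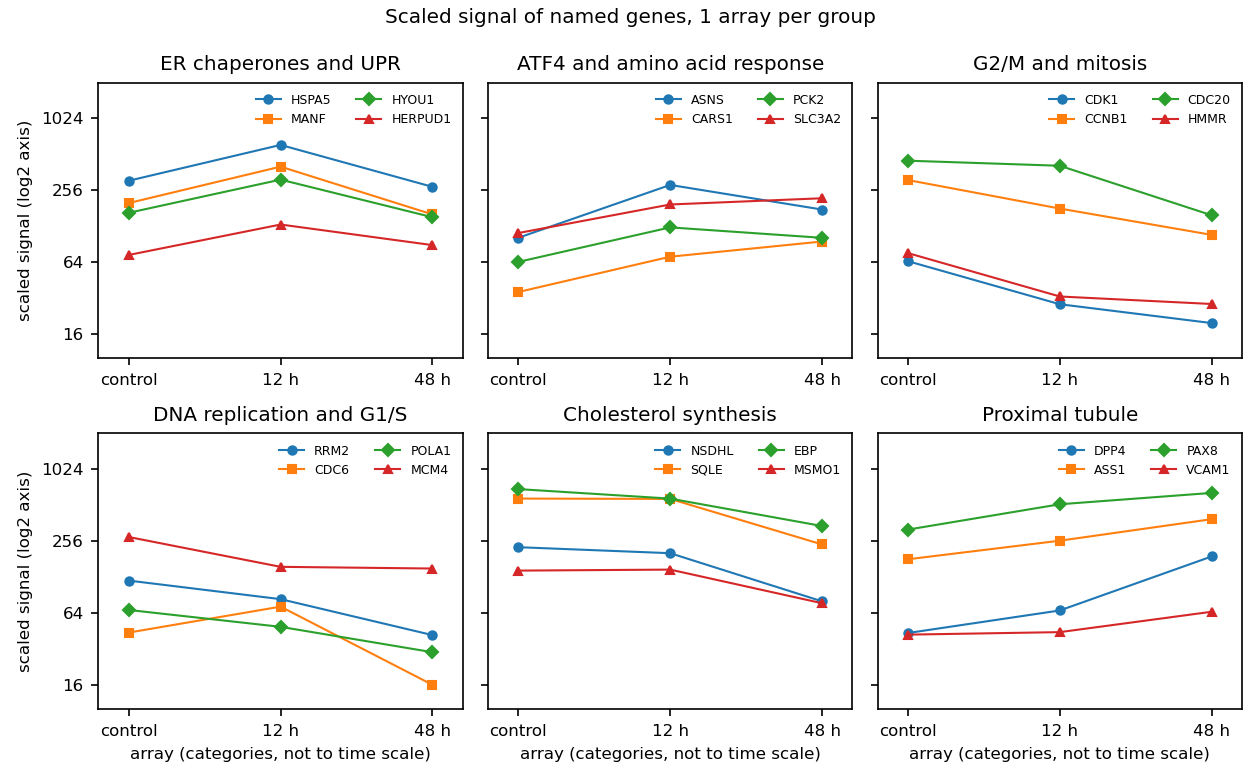
Scaled signal (log2 axis, arbitrary units) of 4 genes from each of 6 gene lists on the control, 12 h and 48 h arrays; each point is 1 array and the lines only join the points of a gene. HSPA5 was highest at 12 h (614), CDK1 was lowest at 48 h (19.7) and DPP4 was highest at 48 h (190.2), relative to the bulk of genes on each array.

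Other lists did not stand apart at 48 h and yet held 3 members at least 2-fold different. Among mesenchymal and cytoskeletal genes linked to epithelial-mesenchymal transition, 13 of 19 were lower, with a median of -0.17 at percentile 11.42. The contractile genes CALD1, TAGLN and MYL9 were 2.54-fold, 2.17-fold and 2.14-fold lower. CALD1 and TAGLN read 12.3 and 12.5 scaled units at 48 h, close to the floor. ACTA2, the smooth muscle actin, was 1.73-fold higher but dim, at 17.5 in the control and 30.4 at 48 h. VIM was 1.23-fold lower and FN1 1.04-fold lower. With the mean of all probe sets of a gene this list had a median of -0.41 (percentile 0.35). Epithelial junction and keratin genes had a median of 0.16 at percentile 85.77, with 3 members at least 2-fold higher. MUC1 was 2.2-fold higher, CDH1 2.12-fold higher at 25.1 scaled units, CD24 2.11-fold higher and KRT18 1.71-fold lower. Collagen and extracellular matrix genes had a median of 0.17 at percentile 94.71. The matricellular genes CCN1 and CCN2 were 3.14-fold and 2.89-fold lower, while LAMB1, a laminin chain, was 2.60-fold and the proteoglycan gene BGN 1.87-fold higher. TGF-beta ligand, receptor and response genes had a median of -0.07 at percentile 28.98 (above 0 with the floor at the 60th percentile); ID3 was 3.49-fold and GDF15 1.95-fold higher. NRF2 and oxidative stress genes had a median of 0.01 at percentile 43.9 (below 0 with quantile normalization), with 14 of 28 higher. The pentose phosphate enzyme TKT was 2.69-fold higher, EPHX1 2.28-fold, AKR1C3 1.94-fold, GCLM 2.01-fold lower, and HMOX1 1.02-fold higher, or slightly lower with quantile normalization. Hypoxia and glycolysis genes had a median of 0.11 at percentile 78.54; PFKL was 2.90-fold, the glucose transporter SLC2A3 2.75-fold, ENO2 2.14-fold and P4HA1 1.87-fold higher. Immediate early and MAP kinase feedback genes had a median of -0.26 at percentile 2.17, with HBEGF 2.27-fold and DUSP5 2.15-fold lower and MCL1 1.72-fold higher; this list passed below percentile 1 with the floor at the 25th percentile (0.35) and with the pseudocount (0.1).

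Genes of the calcineurin pathway, the target of the compound, did not stand apart as a list, with medians of -0.04 at 12 h (percentile 48.84) and -0.04 at 48 h (percentile 40.66), both near 0 and above it under another scaling. The catalytic subunit PPP3CA was 1.03-fold lower at 12 h, a difference that changed sign under other scalings, and 1.35-fold higher at 48 h. PPP3CB was 1.37-fold lower at 12 h and 2.46-fold lower at 48 h, but its other probe set gave log2 ratios of 0.09 at 12 h against -0.45 and -0.23 at 48 h against -1.30. RCAN1, a transcriptional target of calcineurin signalling, read 14.3 in the control and lay at the floor on both exposed arrays. The cell cycle inhibitor CDKN1A was 1.16-fold higher at 12 h and 1.21-fold higher at 48 h, in a list of p53 target genes with medians of 0.14 and 0.23 (percentiles 91.81 and 87.61).

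Other lists lay within the random range at both times. At 12 h and 48 h the medians were 0.16 and -0.12 for matrix protease genes, 0.22 and -0.17 for metallothionein genes, 0.11 and 0.15 for NF-kB and inflammatory mediator genes, and -0.11 and 0.18 for interferon response genes. They were -0.09 and -0.19 for mitochondrial respiratory chain genes, -0.05 and 0.17 for ribosomal protein genes, and -0.01 and 0.08 for apoptosis regulator genes, the 12 h values of the ribosomal and apoptosis lists lying above 0 with median scaling. Distal nephron and collecting duct markers had medians of -0.19 and -0.18 over 8 measured genes, and leukocyte markers 0.05 and 0.10 over 7 (the latter below 0 with the pseudocount). Of the endothelial markers 4 were measured, all dim: PECAM1 read 26.2, 25.7 and 21.9 scaled units, FLT1 23.2, 13.4 and 12.6, TIE1 22.5, 31.3 and 20.5, and CDH5 11.6, 13.7 and 10.6. Among the lists that stood apart at 1 time only, the 12 h median of replication genes was -0.18 (percentile 1.78). With the mean of all probe sets this list lay at percentile 0.82, outside the random range. At 12 h the median was 0.03 for cholesterol and fatty acid synthesis genes and 0.06 for proximal tubule genes. That of proteasome genes was -0.04, and above 0 with median scaling. The 48 h median of the mainly cytosolic heat shock list was -0.15 (percentile 17.3). The 1 measured histone gene, H2AZ1, read 1311, 1062 and 933.7.

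In all, 139 genes were at least 2-fold higher and 102 at least 2-fold lower at 48 h among 3478 measured genes. The serine protease gene HPN was 7.92-fold higher, the secreted inhibitor WFDC2 6.06-fold, the protein kinase C gene PRKCB 4.60-fold with its other probe set at a log2 ratio of 1.34, and DPP4 4.38-fold. The lipase inhibitor G0S2 was 4.31-fold higher, the gap junction gene GJA1 3.66-fold, the antimicrobial peptide gene DEFB1 3.59-fold, ID3 3.49-fold, the perlecan gene HSPG2 3.41-fold (its other probe set gave 0.21 in the 48 h over 12 h log2 ratio against 1.09) and the natriuretic peptide receptor NPR1 3.37-fold. The neuropeptide gene GAL was 5.58-fold lower, HLA-DQB2 4.99-fold, S100A2 4.27-fold, USP4 4.10-fold and the cytokine IL6 4.02-fold. The tubulin gene TUBA1A was 3.87-fold lower, the transferrin receptor TFRC 3.75-fold, the E2F partner TFDP1 3.74-fold, PLAT, the tissue plasminogen activator, 3.66-fold and FABP5 3.54-fold. TFDP1 and IL6 read 12.8 and 13.7 at 48 h, close to the floor. Among genes at the floor on 1 array, KCNMB1 was at least 4.48-fold higher, HOXB5 at least 4.25-fold, ACSM3 at least 3.66-fold, DDC at least 3.59-fold and GSTT1 at least 3.41-fold. KIFC1 was at least 2.88-fold lower, GLIPR1 at least 2.84-fold, PIM2 at least 2.73-fold, COL11A1 at least 2.71-fold and NUP98 at least 2.57-fold.

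At 48 h 7 of the 13 2-fold genes with another probe set had it on the same side by at least 0.32 on the log2 scale, and second probe sets correlated with the first at r = 0.462 across 183 genes. With the floor at the 60th percentile 73 genes were higher and 57 lower, and with the hybridisation controls 65 and 226.

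**Figure D2:**
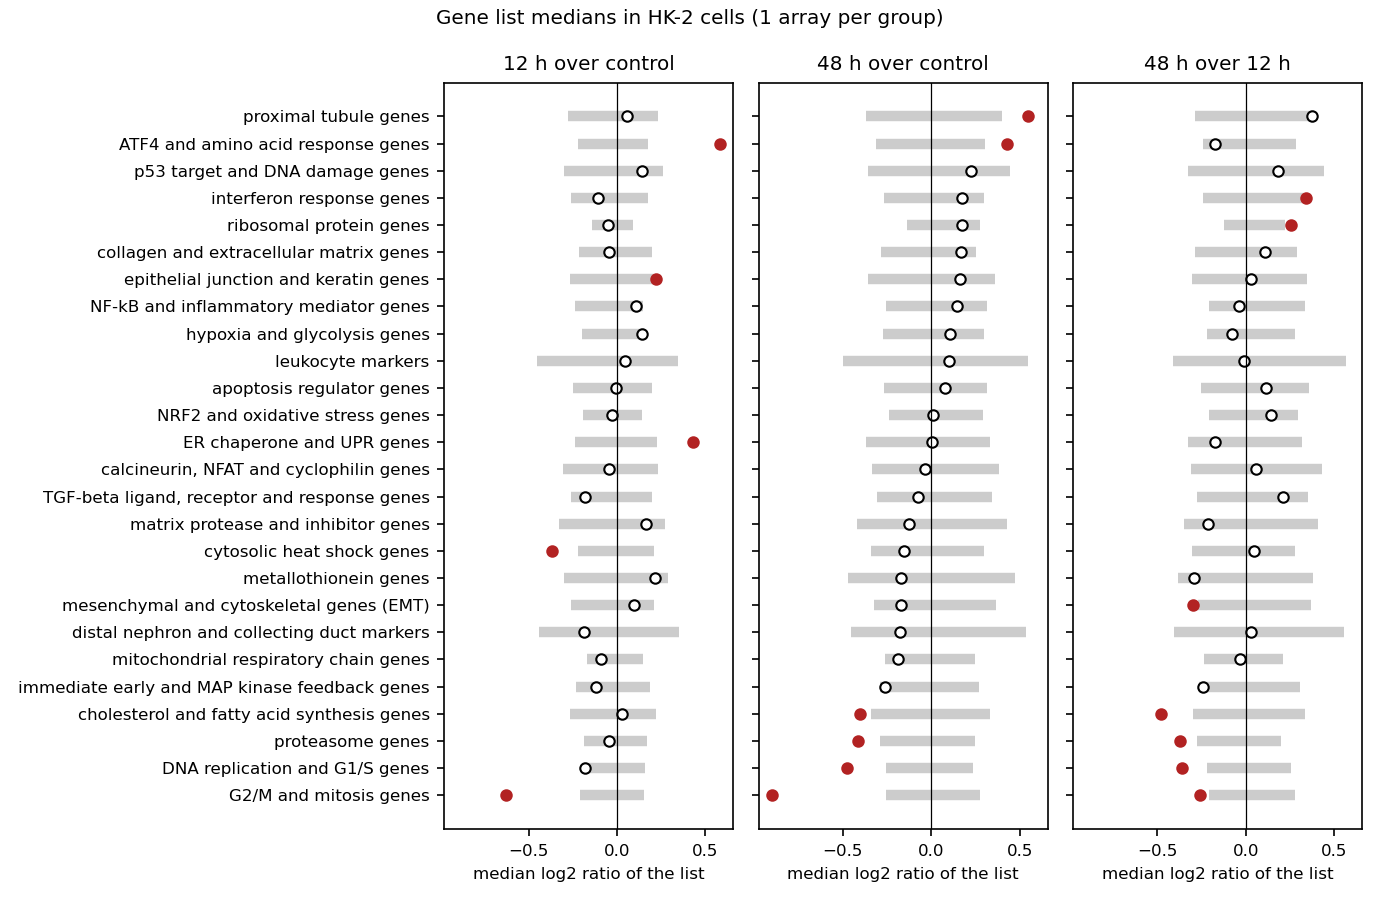
Median log2 ratio of 26 gene lists (points) at 12 h over control, 48 h over control and 48 h over 12 h, with grey bars from the 1st to the 99th percentile of 10000 random lists matched on signal; filled red points lie outside the bar, and there was 1 array per group. The mitosis list lay at -0.63 and -0.90 at 12 h and 48 h over control, and the chaperone list at 0.43 and 0.01, relative to the bulk of genes on each pair of arrays.

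Between 12 h and 48 h, genes of cholesterol and fatty acid synthesis, the proteasome, DNA replication and mitosis were lower at the later time, and ribosomal protein and interferon response genes were higher. The cyclin D1 gene CCND1 read 87.9 scaled units at 12 h and 24.4 at 48 h, while GPNMB, a glycoprotein of lysosomes and melanosomes, read 38.4 and 175.7. Of 17 cholesterol and fatty acid synthesis genes 16 were lower at 48 h than at 12 h, with a median of -0.48 at percentile 0.03. Of 27 proteasome genes 24 were lower, with a median of -0.37 at percentile 0.06, of 31 replication genes 22, with -0.36 at percentile 0.01, and of 29 mitosis genes 22, with -0.26 at percentile 0.24. Of 36 ribosomal protein genes 35 were higher, with a median of 0.26 at percentile 99.66, and of 23 interferon response genes 20, with 0.34 at percentile 99.24. The interferon genes IFI44L and IFI16, named here after their values were seen, were 2.54-fold and 2.37-fold higher. The endoplasmic reticulum chaperone list had a median of -0.17 at percentile 11.69 in this ratio, so its 12 h and 48 h values were not set apart from each other, although 4 of its 16 members were at least 2-fold lower at 48 h. The mesenchymal and cytoskeletal list lay at -0.30, percentile 0.68, with 10 of 18 members lower and 8 higher; it held in 4 of the 7 other settings, and with the floor at the 60th percentile its median turned to 0.014 (percentile 40.48). The ribosomal list held in 5 of 7 and the interferon list in 6 of 7. The 18S probe set was lower at 48 h than at 12 h, with a log2 ratio of -0.74.

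In all, 154 genes were at least 2-fold higher and 85 at least 2-fold lower at 48 h than at 12 h among 3474 measured genes. DBP was 5.46-fold higher, the complement receptor gene C5AR1 5.09-fold, GPNMB 4.58-fold, HPN 4.39-fold and CAMLG 4.30-fold. GAL was 4.71-fold lower, PLAT 4.69-fold, CDC6 4.52-fold, the neurofilament gene NEFH 3.77-fold and CCND1 3.60-fold. With the floor at the 60th percentile 82 genes were higher and 46 lower, and with the hybridisation controls 23 and 998. Of 13 such genes with another probe set 10 had it on the same side by at least 0.32 on the log2 scale, and r was 0.439 across 183 genes.

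The same control array served both exposure times. The genes higher at both times by at least 2-fold numbered 12 and included TGFB1, MAN2B1, ACAA1, EPAS1 and LMAN2. The genes lower at both also numbered 12 and included CDK1, DLGAP5, HMMR, IL6, USP4 and PKLR, and 2 genes differed in opposite directions. PKLR lay at the floor on both exposed arrays, so its ratios are the same bound, set by the control value. The other probe set of IL6 gave a log2 ratio of -0.46 at 12 h against -1.11. Independent lists would share 1.09 and 1.45 genes, and 100 simulations of unchanged arrays sharing 1 control gave 10.8 and 14.97. The log2 ratios at 12 h and 48 h correlated across 2992 genes with r = 0.394, against 0.499 in the simulations, with a covariance of 0.0844 against 0.110. The simulated scatter was taken from the 48 h over 12 h ratios, which also hold real differences and so can overstate it. With 1 control array the shared part cannot be split off, and the overlap does not show a response common to both times.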

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

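The tests on the chaperone list, on a trend with signal in the cell cycle lists, on the control array and on the share of 2-fold genes by signal were chosen after the results had been seen, and those on hours in culture and on second probe sets before.

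Some genes and lists lay on opposite sides of the control at 12 h and 48 h, with 1 array each, and these differences were not tested. The log2 ratios over control at 12 h and 48 h were -0.70 and 1.65 for C5AR1, -0.96 and 1.15 for CAMLG, -1.67 and 0.78 for DBP, and -0.61 and 1.59 for GPNMB. They were 0.48 and -1.37 for CCND1, 0.72 and -1.45 for CDC6, 0.49 and -1.10 for DUSP5, 0.65 and -1.10 for MYL9, 0.90 and -1.02 for NEFH, and 0.36 and -1.87 for PLAT. The median of the mesenchymal and cytoskeletal list was 0.10 at 12 h and -0.17 at 48 h, and that of the ribosomal protein list was -0.048 and 0.17. With median scaling the ribosomal list, and with the mean of all probe sets the mesenchymal list, changed sign at 12 h.

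The 18S ribosomal RNA control probe set, which entered no comparison of genes, was above its control level by a log2 ratio of 2.25 at 12 h and 1.51 at 48 h.

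The endoplasmic reticulum chaperone list was higher than in the control at 12 h and lay at percentile 56.42 of random lists at 48 h, but at percentile 11.69 in the 48 h over 12 h ratio, so the 2 times were not set apart. Cyclic loess removed a trend of only 0.003 on the log2 scale from its members (median), against a list median of 0.43. This argues against a trend with signal between the arrays. That 16 of 16 members lay above the median of all genes (-0.03) follows from all of them being higher than in the control. It was therefore no separate test of a few extreme probe sets. Unequal RNA integrity stays open, since the larger of the changes in 3' over 5' ratio between control and 12 h was 1.45-fold, and the bound for excluding it was set after this value was seen. An error of the single 12 h array stays open as well, since the list did not stand apart at 48 h over control. A response of the cells to the compound, or to 12 h in culture, may also account for the list, and the arrays do not tell these apart.

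The mitosis list was lower at 12 h and 48 h, and the replication list stood apart at 48 h, and at 12 h only with the mean of all probe sets (percentile 0.82). Cyclic loess removed -0.022 at 12 h and 0.013 at 48 h from the mitosis genes (median, log2), against list medians of -0.63 and -0.90, which argues against a trend with signal. The replication list lay at percentile 0.01 in the 48 h over 12 h ratio, which does not use the control array. Unless the single 12 h array is also in error, this argues against an error of the control array as the whole difference at 48 h. The mitosis list had a median of -0.26 in that ratio (percentile 0.24), against -0.90 over control. Much of its difference at 48 h therefore depends on the control array. At 12 h, with 1 control array, such an error stays open. How long the control cells were in culture is not stated, and 0 untreated arrays are known to be of the same age as an exposed one, so hours in culture or crowding and an effect of cyclosporine A cannot be told apart and both may contribute.

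In 5 equal groups of genes ranked from dim to bright, 1.94%, 3.88%, 1.77%, 0.646% and 0.323% were 2-fold different at 12 h and 5.0%, 7.92%, 7.92%, 6.95% and 4.68% at 48 h, and the floor holds the share of the dimmest group down. The 4.68% in the brightest group at 48 h, far above the floor, argues against scatter at low signal as the whole of these differences, while scatter of other kinds stays open. On the same side by at least 0.32 on the log2 scale were the second probe sets of 1 of 4 such genes at 12 h and 7 of 13 at 48 h; 10 of those 13 had the same sign. ELN, with log2 ratios of 1.09 and -1.33 from its probe sets at 12 h, and BCAM, with 1.75 and 0.19 at 48 h, are examples named after their values were seen. The share of second probe sets on the same side met the limit set beforehand for scatter at 12 h. At 48 h it met neither that limit nor the one against scatter. Of measured genes 2.39% were 2-fold different at 12 h and 6.93% at 48 h. The simulation of 48 h over control, whose scatter may be overstated, called 2.63% of unchanged genes. It cannot judge the 12 h share, because its scatter came from the 48 h over 12 h ratios. In the 5 groups these spread by 0.43 to 0.513 on the log2 scale, against 0.306 to 0.412 at 12 h over control. Genes with second probe sets are too few to decide how much of either count may be scatter, and an effect of the compound stays open.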

How the results depend on the processing

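Scaling on the hybridisation controls was the alternative chosen after seeing the data; all others were planned. Median scaling, quantile normalization, cyclic loess and the mean of all probe sets kept each count of 2-fold genes within 1.5 times its main value. No gene chosen by the naming rule and 2-fold different changed direction under any planned setting. PPP3CA at 12 h and HMOX1 at 48 h, both near 0, did. All 155 named ratios shifted by less than the spread of genes of like signal under median scaling, quantile normalization and cyclic loess. With the floor at the 60th percentile 55 moved beyond that spread, and with the mean of all probe sets 16. With the floor at the 25th percentile 10 did, and with the pseudocount 7. With the floor at the 25th percentile, the floor at the 60th, a pseudocount without floor and the hybridisation controls, in that order, 112, 11, 194 and 337 genes were 2-fold higher at 12 h than in the control and 147, 10, 207 and 16 lower. At 48 h over control 225, 73, 277 and 65 were higher and 195, 57, 273 and 226 lower, and at 48 h over 12 h 250, 82, 307 and 23 were higher and 179, 46, 253 and 998 lower. Genes higher at both exposure times numbered 32, 3, 65 and 23 and genes lower at both 48, 5, 67 and 4. A lower floor or none lets dim genes pass and a higher one removes them, and the hybridisation controls shift all genes of an array alike. With the floor at the 60th percentile the mesenchymal list at 48 h over 12 h changed sign to 0.014, and other list medians moved to 0.073 (epithelial), -0.08 (TGF-beta), 0.082 (metallothionein) and 0.047 (hypoxia) at 12 h, to 0.086 (TGF-beta) and 0.32 (collagen) at 48 h, and to -0.61 (matrix protease), -0.035 (ATF4) and 0.13 (NF-kB) at 48 h over 12 h. With the floor at the 25th percentile they moved to 0.20 (proximal tubule) and 0.30 (leukocyte) at 12 h, to 0.34 (proximal tubule), 0.025 (interferon) and 0.23 (apoptosis) at 48 h, and to -0.079 (mesenchymal) and -0.12 (calcineurin) at 48 h over 12 h. The pseudocount gave 0.14 for proximal tubule genes at 48 h, and 0.13 for them and -0.44 for matrix protease genes at 48 h over 12 h. The mean of all probe sets gave -0.046 and -0.41 for mesenchymal genes at 12 h and 48 h and -0.093 for immediate early genes at 48 h over 12 h. Ribosomal protein genes moved to 0.019 at 12 h with median scaling, and to 0.045 at 48 h and 0.103 at 48 h over 12 h with quantile normalization. The cause was not tested for these list medians. Lists inside the random range left it in some settings: replication genes at 12 h with the mean of all probe sets (percentile 0.82), matrix protease genes at 48 h over 12 h with the floor at the 60th percentile (0.3) and the pseudocount (0.25), proximal tubule genes there with median scaling (99.3), quantile normalization (99.2) and the floor at the 60th (99.3), and immediate early genes there with quantile normalization (0.65) and cyclic loess (0.8). The chaperone list at 12 h kept a median between 0.42 and 0.50, the ATF4 list between 0.57 and 0.66 at 12 h and 0.43 and 0.47 at 48 h, the mitosis list between -0.63 and -0.56 at 12 h and -0.91 and -0.87 at 48 h, and the proteasome list between -0.42 and -0.41 at 48 h. Values at or below the floor have no order, and dim genes limit the counts, as their change with the floor shows.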

Other observations

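The tests of the lists in this part were chosen after single genes of the same kind had been seen at 48 h, and their limits were set before the lists' own results were known.

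Lysosomal genes were higher at 48 h than in the control. Of 38 measured lysosomal enzyme and membrane genes, in a list without MAN2B1 and GPNMB, 31 were higher and 7 lower, none of them 2-fold, with a median log2 ratio of 0.41. The membrane proteins LAMP2 and LAMP1 were 1.98-fold and 1.78-fold higher, the protease CTSH 1.89-fold, the ceramidase ASAH1 1.83-fold and the glucosidase GAA 1.75-fold. Proton pump genes were mixed and mostly lower. ATP6V1A was 1.94-fold and ATP6AP1 1.47-fold higher, while ATP6V0B was 1.71-fold, ATP6V1E1 1.34-fold, ATP6V0C 1.22-fold and ATP6V0D1 1.12-fold lower. At 12 h the median was 0.09, at percentile 95.14, and between 12 h and 48 h it was 0.31, at percentile 99.95. The hypothesis that lysosomal genes as a group were higher at 48 h was met by a percentile of 100 among matched random lists, and the 7 other settings gave medians from 0.33 to 0.43 and percentiles of at least 99.9. Whether this difference goes with the compound or with hours in culture was not tested.

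A list of actin cytoskeleton, SRF and YAP target genes was drawn up because CCN1, CCN2, TAGLN, MYL9 and CALD1 were lower at 48 h, and it left these genes out. Of 27 measured members 21 were lower, none of them 2-fold, with a median of -0.26, and CFL1 was 1.91-fold, TPM4 1.87-fold and PDLIM7 1.68-fold lower. At 12 h over control the median was 0.13, at percentile 96.56, and at 48 h over 12 h it was -0.28, at percentile 0.38, with 22 of 26 members lower. The hypothesis that such genes as a group were lower at 48 h than in the control was not decided, since the list lay at percentile 1.40 and between 0.6 and 4.7 under the 7 other settings, around the limit of percentile 1.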
